A study of Mus musculus with 6 samples.

How the data were processed

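CTCF ChIP-seq was performed on muscle stem cells (satellite cells) of C57BL/6 mice carrying a Pax7-nGFP reporter, at postnatal day 38 per the labels. The series holds 6 samples. Quiescent satellite cells (QSC) and freshly isolated satellite cells (FISC) have 2 CTCF ChIP libraries and 1 input library each. ChIP-seq sequences the DNA that is recovered with an antibody, here against the chromatin architecture protein CTCF, after the chromatin has been sonicated. The design text of the series describes Hi-C library preparation, which is not the assay analysed here.

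The authors deposited 1 peak list per state, 2 lists in all, as intervals with a chromosome, a start and an end. The deposited lists give no height, fold, score or p-value per peak, so the authors' threshold could not be made stricter and peaks could not be ranked by strength. Per the submitters' processing notes, the genome build is mm9, and the tools named are Bowtie2 2.2.3, Picard, MACS2 and HOMER, with no role or order given. How the 2 libraries of a state entered its list, the calling threshold, and the use of the input library are not given in the sources used here. The depth of the libraries is unknown, since the lists hold no read counts. The number of peaks in a list rises with depth and with a looser threshold, so the numbers of peaks in the 2 lists are not a measure of total CTCF binding. Each state has a single list. No value has a replicate error, and every test below compares 2 lists, not 2 replicated conditions.

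The build was checked on the coordinates. On 9 of 20 chromosomes a listed peak lay beyond the last gene of the GRCm38 gene table, by 7146 kb on chromosome 7, so the lists are not in GRCm38 coordinates. Because no mm9 genome or annotation was used here, the planned comparisons of promoters, exons and introns, of gene lists and of CTCF motifs were not run, and peaks carry no gene names. Coordinates are mm9 and count from 1.

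Overlaps, windows and tests were computed with Python 3.11.15, numpy 2.4.6 and scipy 1.17.1. A peak was called shared when it overlapped a peak of the other list by at least 1 bp, and QSC-only or FISC-only otherwise. The shared numbers were checked with bedtools 2.31.1, which gave the same counts. Chance overlap came from 1000 placements of the FISC peaks at random positions on their own chromosomes, between the first and the last listed position. Shares carry 95% Wilson intervals, which cover counting error only. Chromosome shares were compared with Fisher's exact test, two-sided, with Benjamini-Hochberg (BH) adjustment over 20 chromosomes. As neighbouring peaks are not independent, odds ratios also carry a 95% interval from 2000 bootstrap resamples of 10 Mb blocks. State-only peaks were counted by midpoint in 1 Mb windows, and each window with at least 10 of them was compared with the rest of the genome by the same test. Widths of shared and state-only peaks were compared by a permutation test on the difference of medians, with 100000 permutations across peaks, which are not replicates.

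Tests, windows and the rule for named regions were fixed before the data were examined. The rule names, for each class of peak, the 5 windows of 1 Mb with the most peaks, and windows tied with the fifth were kept. The comparison of interval widths between classes, the split by number of shared peaks per window, the distances to shared peaks and the spread of each list over windows were added after seeing the data. Alternatives changed the definition of a shared peak, the size of the lists, the chromosomes, the window size and the way of shuffling.

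The procedures were tested on simulated data. With 40% of the 19403 QSC peaks copied into a simulated second list, 40.7% were recovered as shared. The copies were shifted by less than a peak width and so overlapped by construction, which checks the counting only. Chromosomes that had lost 40% of their FISC peaks were called in 100% of 100 cases, and 4% of 900 other chromosomes were called. Windows with 15 or more state-only peaks, 95% of them from QSC, were called in 71.7% of 300 cases. For windows with 10 to 14 such peaks that rate was 2.33%, so the window test detects only large imbalances in windows rich in peaks. In the simulations of chromosomes and windows each peak drew its list independently, without the regional clustering of the real lists. These rates therefore do not give the rate of false calls in the real lists. Each window run held 30 imbalanced windows, all with a QSC-only excess. That many true imbalances ease the BH adjustment, so the test can detect a smaller share where fewer windows are imbalanced. A FISC-only excess was not simulated.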

Results

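CTCF occupancy was profiled in satellite cells, the Pax7-expressing stem cells of skeletal muscle, in a quiescent state (QSC) and after fresh isolation (FISC). Removing these cells from muscle is known to start their activation, and the series title places the data in a study of chromatin architecture during activation and aging. CTCF is a zinc finger protein that binds a long DNA motif and, with cohesin, anchors chromatin loops and domain boundaries. The comparison asks which CTCF sites were listed in both states and which in 1 state only. Each state has 2 ChIP libraries and 1 input library in the series and is represented by 1 peak list, so no listed value has a replicate error.

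The QSC list held 19403 peaks and the FISC list 17520. QSC peaks were narrower, with a median width of 310 bp (95% bootstrap interval 309 to 312) against 372 bp (370 to 374) in FISC. The narrowest interval was 245 bp in both lists. The peaks covered 6.63 Mb of the genome in QSC and 6.82 Mb in FISC. FISC peaks lay closer together, with a median spacing of 48.5 kb against 72.1 kb in QSC. The next peak was under 10 kb away for 18.6% of FISC gaps and 11.5% of QSC gaps. Without read depths or replicate lists, these differences between the lists cannot be set against a replicate spread.

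A core set of CTCF sites was listed in both states, and the larger part of each list was not. Of the QSC peaks, 7329 (37.8%, 95% Wilson interval 37.1 to 38.5) overlapped a FISC peak, and 12074 (62.2%) were QSC-only. Of the FISC peaks, 7325 (41.8%, 41.1 to 42.5) overlapped a QSC peak, and 10195 (58.2%) were FISC-only. Merging both lists gave 29579 sites, of which 7310 (24.7%) were in both. Random placement gave a mean of 101 shared QSC peaks and at most 135 over 1000 shuffles, so the observed overlap was 72.5-fold above chance (one-sided permutation of positions, p = 0.001, the smallest that 1000 shuffles can give). Against local shuffles, which moved each peak by at most 500 kb and were added after seeing the data, the overlap of QSC peaks was 45.5-fold above chance. A peak missing from a list was not called there, which does not show that CTCF was absent from the site.

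At the 7280 sites where a single QSC peak met a single FISC peak, the 2 midpoints lay a median of 54 bp apart. The midpoints were within 100 bp of each other at 75.8% of these sites (95% Wilson interval 74.8 to 76.8). The FISC interval was the wider at 63.6% of them (62.5 to 64.7), with a median log2 width ratio of FISC to QSC of 0.16 (95% bootstrap interval 0.15 to 0.18).

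Shared sites were wider than state-only sites in both states. In QSC, the median width was 359 bp (95% bootstrap interval 356 to 362) for shared peaks and 291 bp (290 to 293) for QSC-only peaks. In FISC, it was 412 bp (409 to 414) for shared peaks and 344 bp (341 to 346) for FISC-only peaks. Both differences were 68 bp, with a permutation p of 1e-05, the smallest that the permutations can give. Among the narrowest 10% of QSC peaks 16.2% were shared, and among the widest 10% 77.6% (75.7 to 79.4). The FISC list went from 14.1% in the narrowest 10% to 68.6% (66.4 to 70.7) in the widest. Thus 31.4% of the widest FISC peaks and 22.4% of the widest QSC peaks had no partner in the other list.

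**Figure D1:**
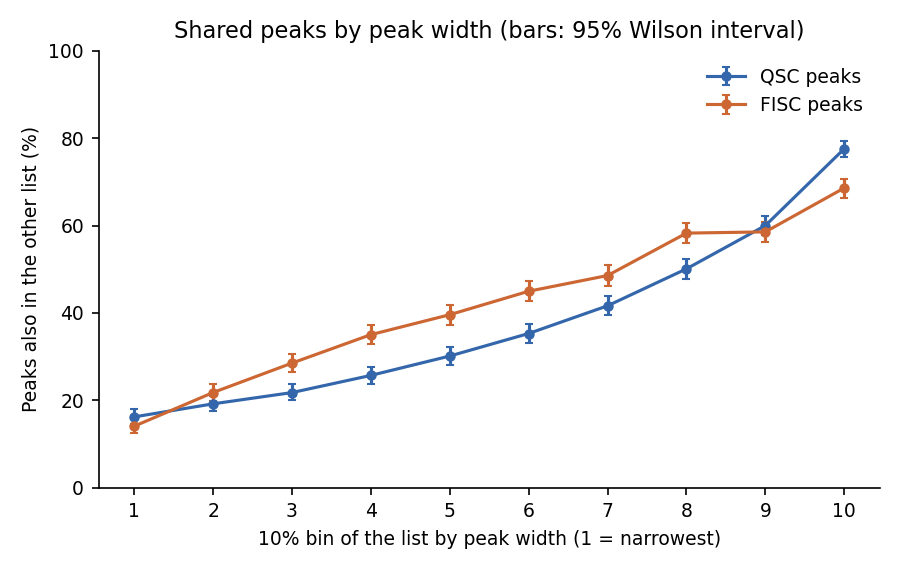
Percentage of peaks that overlap a peak of the other list (y axis) for each 10% of a list by peak width (x axis, 1 is the narrowest), in QSC (blue) and FISC (orange), with 95% Wilson intervals. The share was 16.2% and 14.1% in the narrowest 10% and 77.6% and 68.6% in the widest 10% of the QSC and FISC lists.

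The X chromosome differed most between the lists. It held 733 QSC peaks (3.78% of the list, 95% Wilson interval 3.52 to 4.06) and 396 FISC peaks (2.26%, 2.05 to 2.49). The odds ratio of QSC over FISC was 1.70, or 0.76 on the log2 scale (95% bootstrap interval 0.51 to 1.09; Fisher's exact test, BH adjusted p = 3.29e-16). The log2 odds ratios of the 19 autosomes ran from -0.32 to 0.21. There were 1.85 QSC peaks per FISC peak on X and 1.09 on the autosomes. All 17 blocks of 10 Mb along X held fewer FISC than QSC peaks. Sharing was also lower on X, where 13.8% of QSC peaks (95% Wilson interval 11.5 to 16.5) and 25.5% of FISC peaks (21.5 to 30.02) had a partner. On single autosomes these shares ran from 32.6% to 49.7% in QSC and from 38.8% to 44.7% in FISC.

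Among the autosomes, chromosomes 11 and 19 took a larger share of the FISC list, and chromosome 3 of the QSC list. Chromosome 11 held 1374 FISC and 1235 QSC peaks (log2 odds ratio of QSC over FISC -0.32, 95% bootstrap interval -0.45 to -0.16; Fisher's exact test, adjusted p = 3.49e-07). It was also the chromosome with the highest share of QSC peaks that had a FISC partner, 49.7%. Chromosome 19 held 594 FISC and 546 QSC peaks (-0.28, -0.45 to -0.05; exact test, adjusted p = 0.00936). In the wider 50% of each list chromosome 19 no longer passed the exact test (adjusted p = 0.424). Chromosome 3 held 1061 QSC and 836 FISC peaks (0.21; exact test, adjusted p = 0.0126), but its bootstrap interval over blocks reached from -0.00385 to 0.49 and so included 0. The other 16 chromosomes did not pass the test, with adjusted p of 0.121 or more. A single QSC peak lay on the mitochondrial chromosome and no FISC peak did.

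**Figure D2:**
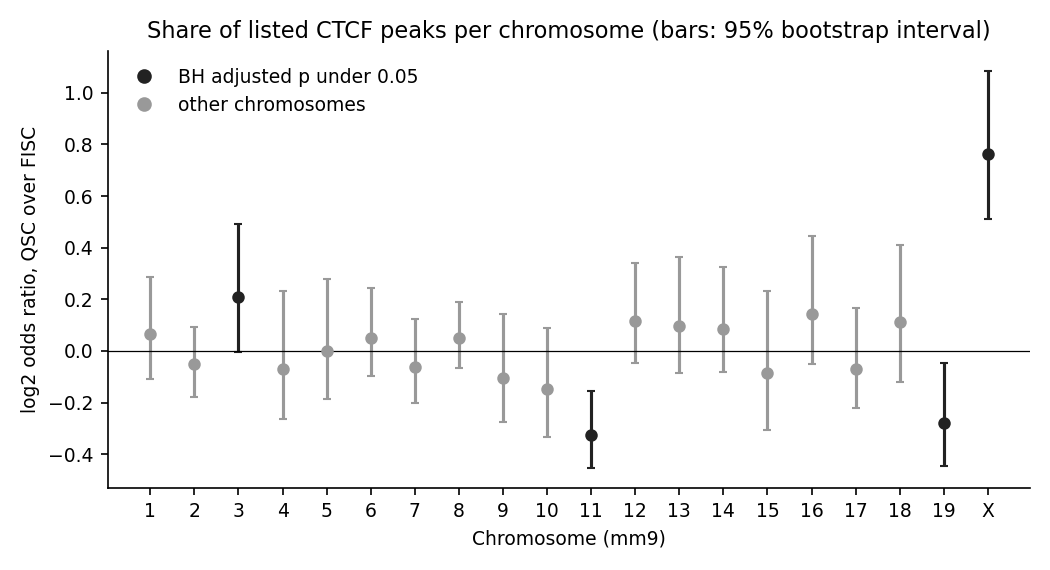
Log2 odds ratio of a chromosome's share of the QSC list over its share of the FISC list (y axis) for each chromosome (x axis, mm9). Points are the estimates, bars the 95% interval over 10 Mb blocks, and black points passed Fisher's exact test after BH adjustment. X stands at 0.76 and the autosomes between -0.32 and 0.21.

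At the scale of 1 Mb, windows rich in sites of one class tended to hold sites of the others. Across the 2547 windows with any peak, the numbers of QSC-only and FISC-only peaks had a Spearman rho of 0.309, a description across windows, which are not replicates. The richest window lay at 80 to 81 Mb of chromosome 10, with 28 shared, 14 QSC-only and 23 FISC-only peaks. The adjoining window at 79 to 80 Mb held 22 shared, 10 QSC-only and 24 FISC-only peaks, the most FISC-only peaks of any window. Over these 2 Mb, 50 of 74 QSC peaks and 50 of 97 FISC peaks were shared. Windows rich in shared sites also included chromosome 15 at 78 to 79 Mb with 26 shared peaks, chromosome 2 at 32 to 33 Mb with 22, and chromosome 8 at 73 to 74 Mb and chromosome 17 at 35 to 36 Mb with 21 each.

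**Figure D3:**
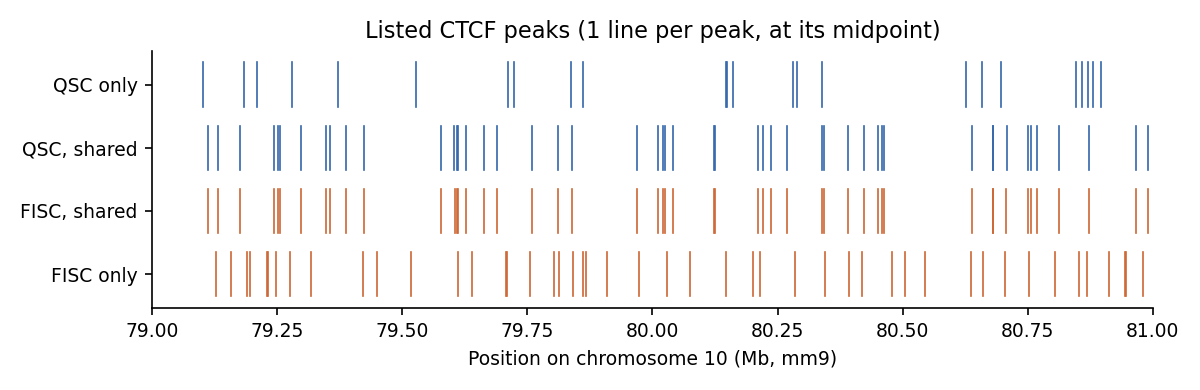
Positions of all listed CTCF peaks from 79 to 81 Mb of chromosome 10 (x axis, Mb, mm9), drawn at their midpoints in 4 rows for QSC-only, shared (QSC and FISC coordinates) and FISC-only peaks. The region holds 74 QSC and 97 FISC peaks, with 50 of each list shared.

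The windows with the most FISC-only peaks, besides the pair on chromosome 10, lay at 98 to 99 Mb of chromosome 15, at 96 to 97 Mb of chromosome 11 and at 151 to 152 Mb of chromosome 4. They held 22 FISC-only and 10 QSC-only, 21 and 4, and 20 and 11 peaks. The windows with the most QSC-only peaks lay on chromosome 2 at 25 to 26 Mb and at 30 to 31 Mb, on chromosome 10 at 80 to 81 Mb, on chromosome 11 at 102 to 103 Mb, on chromosome 13 at 7 to 8 Mb and on chromosome 15 at 78 to 79 Mb. Each held 14 or 15 QSC-only peaks. All but the chromosome 13 window also held between 10 and 23 FISC-only peaks. The chromosome 13 window held 15 QSC-only peaks and no other peak of either list.

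No single 1 Mb window passed the test of imbalance after adjustment. Fisher's exact test on the 901 windows with at least 10 state-only peaks gave 0 windows with an adjusted p under 0.05 and 91 with an unadjusted p under 0.05. Of these 91, FISC-only peaks were in excess in 71 and QSC-only peaks in 20, but this balance turned with the window size. At an unadjusted p under 0.05, Fisher's exact test gave 49 windows of 500 kb with a FISC-only excess and 0 with a QSC-only excess, and 78 and 106 windows of 2 Mb. The minimum of 10 state-only peaks was kept, so 363 windows of 500 kb and 1073 of 2 Mb were tested. Small windows reach that minimum only where peaks are dense, so the kind of region tested changed with the window size. The lowest adjusted p was 0.0667, shared by the chromosome 13 window at 7 to 8 Mb and the chromosome 11 window at 96 to 97 Mb. With 2 Mb windows 4 windows passed, and the test had little power for windows with few peaks.

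FISC peaks were spread less evenly over the genome than QSC peaks. Over 2589 windows of 1 Mb the variance of the number of peaks was 7.13 times its mean in the full FISC list (95% bootstrap interval 6.53 to 7.66) and 3.40 times in the full QSC list (3.08 to 3.70). No peak was listed in 14.1% of the windows in FISC (12.3 to 16.1) and in 2.202% in QSC (1.35 to 3.22). Split by shared peaks, FISC-only peaks were more numerous where shared peaks were dense. A shared peak needs a call in both lists, so a region poorly called in FISC loses shared and FISC-only peaks together, and this split cannot separate that from a regional difference. In the 844 windows with no shared peak, a window held a mean of 4.06 QSC-only peaks (95% bootstrap interval 3.91 to 4.20) and 1.23 FISC-only peaks (1.14 to 1.33). In the 272 windows with 8 or more shared peaks the means were 6.57 (6.23 to 6.88) and 10.2 (9.70 to 10.7). FISC-only peaks thus made up 23.3% (95% Wilson interval 22.1 to 24.6) of the state-only peaks in the first group of windows and 60.8% (59.4 to 62.2) in the last. The median distance to the nearest shared peak was 63.5 kb (95% bootstrap interval 57.7 to 71.6) for FISC-only peaks and 164 kb (143 to 188) for QSC-only peaks, a ratio of 2.58 (2.33 to 2.83). On all 20 chromosomes tested the FISC-only median was the lower one. Within 10 kb of a shared peak lay 15.9% of FISC-only peaks (15.2 to 16.6) and 7.89% of QSC-only peaks (7.42 to 8.38).

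**Figure D4:**
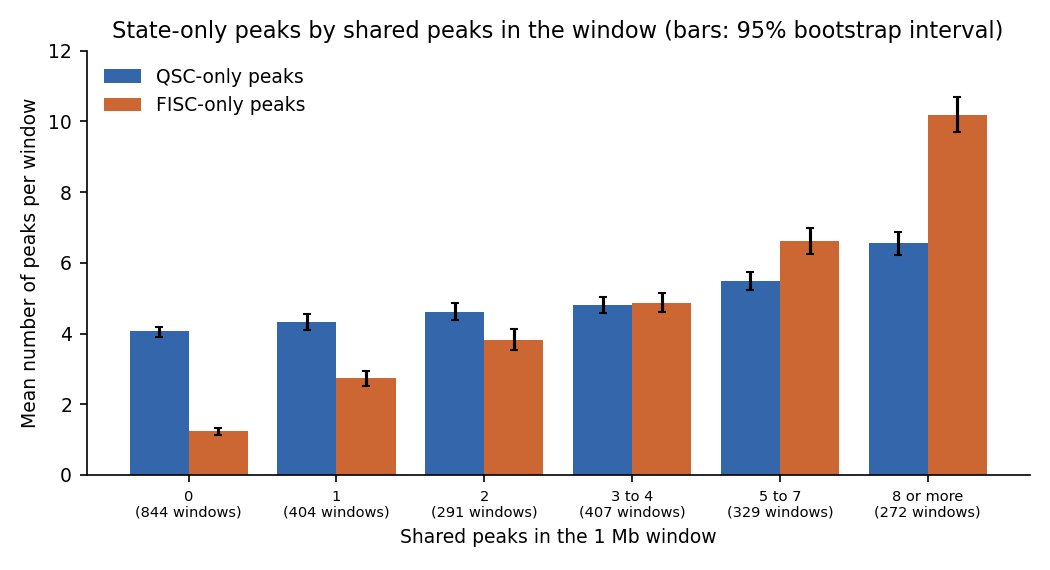
Mean number of QSC-only (blue) and FISC-only (orange) peaks per 1 Mb window (y axis) by the number of shared peaks in the window (x axis, with the number of windows). Error bars are 95% bootstrap intervals over windows. FISC-only peaks went from 1.23 to 10.2 per window and QSC-only peaks from 4.06 to 6.57.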

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

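Of the 34 values recomputed under an alternative, 30 kept their direction and their side of the threshold or stayed within set limits. For median widths the limit was their 95% bootstrap interval, and for counts 1.5 times the reported count, which does not say that the same chromosomes or windows passed. The other 4 moved: a count of windows, and the ratio of distances under 3 alternatives, which kept its direction. The overlap stayed above chance under every definition and list tried. The shared part of QSC peaks ran from 28.5% to 39.1% and that of FISC peaks from 31.5% to 43.3%, lowest with midpoints within 100 bp and highest with peaks within 500 bp. The lowest excess over chance was 31.8-fold, with peaks within 500 bp. Local shuffles gave 45.5-fold for QSC and 45.2-fold for FISC peaks. The odds ratio of X was 1.70 with equal list sizes, 1.85 for state-only peaks and 2.13 for the wider 50% of each list. The number of chromosomes that passed went from 4 to 5 in the wider 50% of each list, where chromosome 19 lost its call (adjusted p = 0.424 by the exact test) and chromosomes 7 and 18 gained one. It was also 5 among state-only peaks, where chromosome 10 gained one. The number of windows that passed rose from 0 to 4 with 2 Mb windows, where each window holds more peaks. FISC-only peaks were in excess at chromosome 10, 60 to 62 Mb (31 against 7), chromosome 11, 96 to 98 Mb (37 against 11), and chromosome 19, 44 to 46 Mb (21 against 4). QSC-only peaks were in excess at chromosome 4, 90 to 92 Mb (16 against 0). The ratio of median distances to shared peaks was 2.30 without peaks within 10 kb of a shared peak, 2.32 with shared peaks called anew between the wider 50% of each list, and 2.98 for the wider 50% of each list with the full lists deciding which peaks are shared. The cause of these changes was not tested. The wider 50% of peaks, the local shuffles, the comparisons without X in the windows or totals, and the alternatives for distances were chosen after seeing the data. The stricter threshold was not run, since the lists hold no score. The alternatives for annotation, gene lists and motifs were not run without an mm9 reference. No paired analysis was possible because each state has 1 list with no values per replicate, and for the same reason no replicate could be left out. The unknown depth limits all statements on peaks found in 1 list.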

Other observations

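The tests of matching on QSC peaks, of intervals within 10 kb and of distances of the wider 50% of peaks were chosen only after the results they bear on were seen.

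The widest interval of both lists lay at the same place on chromosome 17. It ran from 39979966 to 39985776 in QSC, 5811 bp, and was listed in FISC as 3849 bp from 39979990 and 1828 bp from 39984003. The next widest interval was 1449 bp in QSC and 1848 bp in FISC. The mitochondrial QSC peak ran from 15420 to 16214. No region was removed from the lists, and whether these intervals reflect CTCF binding was not tested.

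Most listed peaks were in 1 state only. A candidate explanation is that CTCF was bound in both states and the weaker sites fell under the calling threshold in 1 list. The narrower widths of state-only peaks go with this. As the whole cause, with lists of like depth and width following strength, this explanation would leave nearly all of the widest peaks shared. A peak of the other list lay within 500 bp of 69.6% (95% Wilson interval 67.4 to 71.7) of the widest 10% of FISC peaks. For the widest 10% of QSC peaks this was 78.0% (76.1 to 79.8). Depth and threshold are unknown and width is only a stand-in for strength, so this cannot exclude thresholds even as the whole cause. A change of CTCF binding between the states also stays open, untested for lack of replicate lists.

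The X chromosome took a larger share of the QSC list. The larger share was not confined to narrow intervals, since in the wider 50% of each list the odds ratio was 2.13 (95% bootstrap interval 1.58 to 3.26). This does not exclude an effect of the calling limit. A weaker X signal in FISC would narrow or remove FISC peaks there and raise that ratio. The wider 50% held 125 of 396 FISC peaks and 290 of 733 QSC peaks on X. Low regional density stays open. Matched on QSC peaks alone, X had 0.540 FISC peaks per QSC peak (95% bootstrap interval 0.438 to 0.645). The value was 0.675 (0.623 to 0.728) in 82 autosomal blocks of 10 Mb and 0.917 on all autosomes. X thus lay below the interval of the matched blocks, and the matched blocks lay below all autosomes. The first 2 intervals overlap, which is not a test of their difference, and that difference was not tested. Whether density covers all of the X difference is undecided. Matching 1 Mb windows on shared peaks (FISC-only peaks 31.8% of the state-only peaks on X, 32.6% in autosomal windows) decides nothing, since a peak is shared only if FISC lists it. Fewer X copies among the mice used for FISC, whose sex the labels do not give, could not be excluded: at 101 shared sites on X the log2 width ratio of FISC to QSC differed from autosomes by 0.0108 (95% bootstrap interval -0.15 to 0.08; permutation p = 0.851), too wide an interval to decide.

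FISC-only peaks lay closer to shared peaks than QSC-only peaks did. Sites listed as several intervals in FISC are argued against as the whole cause. The ratio of median distances was 2.30 (2.06 to 2.52) without peaks within 10 kb of a shared peak. With those peaks it was 2.58 (2.33 to 2.83), so a part is not excluded. The unequal chromosome shares do not account for the difference in distance, since the FISC-only median was lower on 20 of 20 chromosomes. Intervals narrower than the median of their own list are also argued against as the whole cause. The ratio was 2.98 (2.61 to 3.43) for state-only peaks in the wider 50% of their own list. It was 2.32 (2.07 to 2.66) with shared peaks called anew between those parts. The wider 50% began at 310 bp in QSC and 372 bp in FISC, so it still held QSC intervals that are narrow for FISC. Width is only a stand-in for strength, so weak QSC calls spread evenly over the genome are not excluded. Mean QSC-only peaks per window went from 4.06 with 0 shared peaks to 6.57 with 8 or more, against 1.23 to 10.2 for FISC-only peaks. Also left open are that peaks listed after isolation may gather in regions already rich in CTCF sites, and that some regions were poorly called in FISC, which removes shared and FISC-only peaks together. Reads and inputs would be needed to test these.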
